A study of Homo sapiens with 3 samples.

How the data were processed

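Input and anti-C/EBPβ precipitated DNA of 3 biological replicates of LAP-expressing Hep3B cells was amplified by ligation-mediated PCR, and 4 µg was labelled per channel, per the labels' protocols. The array files hold the deposited intensity of each spot in both channels, as scanned and as processed by Agilent Feature Extraction 9.5.1.1. Per the file headers, the processed intensity had its background subtracted from negative controls, was detrended and was dye-normalised by a linear factor. The deposited log10 ratio of the processed signals (Cy5 over Cy3) is not centred, per the file headers and a comparison with the signals. A deposited table gives 1 log2 ratio per replicate for part of the probes, and how those probes were chosen is not recorded. The files name no genome build, so coordinates are printed as the files give them.

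From the array files, log2 of processed Cy5 over processed Cy3 was taken per probe, which is log2 IP/input. Control spots and spots marked as outliers by the scanner software were left out, 474392 probes had a position, and each array was centred on its median. Before centring the medians of replicates 1 to 3 were -0.01, 0.08 and 0.08. A window joined a probe with all probes whose middle lay within 500 bp, needed at least 3 probes (median 5), and took their mean per replicate. Limma 3.58.1 in R 4.3.3 tested each window's mean of the 3 replicates against 0, two-sided, with Benjamini-Hochberg adjustment over all windows. Enriched meant an adjusted p under 0.05 and a mean log2 of at least 1, depleted a mean of -1 or less, and a gene was bound if any of its windows was enriched. All 3 replicates form 1 group, and the ratio pairs IP and input of a replicate on each array. Their small number limits the precision.

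Probes were assigned to genes by the symbols in the files. Of 17133 symbols, 16596 were matched by accession to a RefSeq table of assembly GRCh38.p14, used for names only, and 17120 genes resulted. The lists were acute phase, complement and coagulation, plasma proteins and apolipoproteins, gluconeogenesis with amino acid and urea metabolism, xenobiotic and bile acid metabolism, liver transcription factors, C/EBP and related factors, cytokines with chemokines and receptors, unfolded protein and amino acid stress response, cell cycle and apoptosis, adipogenesis and lipid storage, myeloid genes, neuronal synapse genes, ribosomal proteins and olfactory receptors. They were tested with Fisher's exact test on bound genes and with limma's camera on gene means, with a preset correlation of 0.01 and with an estimated one. Lists, tests, thresholds, the rule for named genes and a set of other settings were fixed before the data were examined. That rule takes bound genes first, then for each list without a bound member the 2 members with the highest window, and always HP, CRP, SAA1, ALB, PCK1, IL6, CXCL8, CEBPB, CEBPA, CEBPD, DDIT3, SERPINA1, ORM1, C3 and G6PC1, each at the window with the highest mean. It gave 44 genes, and all others were chosen after their values were seen.

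Counts of list members in the highest 1% of a replicate's windows were compared with 10000 random lists matched on windows per gene in 20 bins. The window test, camera, Fisher's test and the random lists were tested on simulated data made from shifted copies of the real ratios with known changes. That set held other background corrections (normexp with offset 50), loess with span 0.3, other centring, filters on dim or saturated spots, windows of 250 and 1000 bp, window medians, single probes, other thresholds, another prior, slides apart, unpaired channels, the deposited table and leaving out each replicate. Centring within probe length, scaling to equal spread, limma's array weights, the counts in highest windows and most alternatives for camera and agreement were added after the data were seen. No genome sequence of the files' build was available, so the planned search for the C/EBP motif was not run. The figures were drawn with matplotlib 3.10.9.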

Results

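The data are 3 biological replicates of 1 experiment in Hep3B, an established human hepatoma line. The cells carried a Tet-OFF construct for flag-tagged LAP, the long activating isoform of the transcription factor C/EBPβ, and had been kept for 10 days without doxycycline, the drug that holds such a construct off. Chromatin was precipitated with 10 µg of an antibody to C/EBPβ, and the recovered DNA (IP, labelled with Cy5) was hybridised together with total input DNA (labelled with Cy3) to promoter tiling arrays. Each replicate used 2 slide designs with different probes, which makes 6 arrays. The input signal was well above background for 84.3% to 86.5% of probes on the arrays of replicate 1, for 97.2% to 97.4% in replicate 2 and for 96.9% to 97.6% in replicate 3. There was no mock precipitation, no culture with doxycycline and no exchange of the dyes, so a dye effect does not cancel in these ratios.

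The comparison of IP with input asks which promoters carried C/EBPβ in LAP-expressing hepatoma cells, where the series title names the transcriptional signature of LAP and of the short isoform LIP. No promoter window was called enriched across the 3 replicates. Among liver genes with textbook roles as C/EBP targets, haptoglobin (HP), an acute-phase haemoglobin scavenger, had a window at 0.86 ± 0.80 (log2 IP/input, SD, n = 3). SERPINA1, which encodes a plasma protease inhibitor, stood at 0.90 ± 0.61, albumin (ALB) at 0.58 ± 0.86, and PCK1, a gluconeogenic enzyme, at 1.11 ± 1.88. Of the 14 genes chosen in advance that had a window, 11 had a ratio above 0 in all 3 replicates at that window, which was picked as each gene's highest. Among all 44 named genes, which include members of control lists, 31 did so at windows picked the same way. The share over all genes was not computed, so the 11 are no sign of binding by themselves. Most values of the 14 genes rested on replicate 1, where window ratios had an SD of 1.01, against 0.39 and 0.48 in replicates 2 and 3. Picking the highest mean favours windows high in that replicate, so part of the fall without it comes with the choice. Without replicate 1, 11 of the 14 fell by more than 1.5 times, with HP at 0.41, ALB at 0.085 and PCK1 at 0.039. SERPINA1 stood at 0.84, with 0.24 and 1.44 in replicates 2 and 3, at a window -3899 bp from its start. With normexp background correction and all replicates the values were lower too, with HP at 0.058, ALB at 0.069, PCK1 at 0.043 and SERPINA1 at 0.21. Part of that drop comes with the setting, whose offset of 50 in both channels pulls ratios toward 0.

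The other genes of that advance choice had windows at 0.38 ± 0.26 (CRP), 0.80 ± 0.90 (SAA1), 0.98 ± 1.49 (C3) and 0.81 ± 0.71 (G6PC1, the glucose-releasing phosphatase). The window of SAA1 is also annotated to SAA2 and lies at -8333 bp from the SAA1 start. The cytokine genes IL6 and CXCL8 had 1.16 ± 1.25 and 0.77 ± 1.43. Within the C/EBP family, CEBPA had 0.92 ± 0.63, CEBPD 0.66 ± 1.63, CEBPB itself 0.46 ± 0.40 and DDIT3 0.55 ± 0.47 (SD, n = 3 for each). The window of DDIT3 is also annotated to MBD6. Without replicate 1, CEBPD and CXCL8 were at -0.27 and -0.027, SAA1 at 0.29, C3 at 0.12, G6PC1 at 0.40, IL6 at 0.45, CEBPA at 0.56 and DDIT3 at 0.34, while CRP was at 0.26 and CEBPB at 0.56. CEBPB was highest in replicate 3 (0.26, 0.21 and 0.92 in replicates 1 to 3) and at 0.23 without it. The mean of CEBPB was -0.057 in windows of 1000 bp to each side. ORM1 had no window on the arrays.

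With limma, 0 of 424594 windows at 16825 genes passed an adjusted p of 0.05 with a mean log2 of at least 1 (smallest adjusted p = 0.844), and 0 passed at a mean of -1 or less. At an unadjusted p under 0.05 there were 10256 windows, or 2.42%, of which 4107 had a ratio above 0 and 6149 below. That split depended on the processing, with 7966 above and 2704 below without centring, 187 and 12950 with normexp, and 0 and 2660 with an intensity trend and a robust prior. Single probes gave 0 calls of 468788 as well (smallest adjusted p = 0.801), with 16180 under the same unadjusted p. In shifted copies of these arrays with known enrichments added to 200 windows, 0 were recovered at log2 1, 2 or 3 and 195 (97.5%) at log2 4. With 2000 such windows, 0 were recovered at log2 1 or 2 and 1966 (98.3%) at log2 3. At the simulated sizes with 0 recovered, enrichment was not detectable at this spread between replicates, and sizes between the simulated ones were not run.

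Leaving out replicate 1 changed the calls. The limma fit of replicates 2 and 3 alone called 72 enriched windows at 40 genes and 1030 depleted windows at 503 genes. The enriched windows included CSF3R, the receptor for granulocyte colony-stimulating factor (0.66 and 3.28 in replicates 2 and 3), NFKBIA, an inhibitor of NF-κB (-0.76 and 4.15), SEL1L, a factor of protein degradation at the endoplasmic reticulum (2.21 and 0.96), and HAL, the histidine-degrading enzyme (0.78 and 2.03). In 67 of the 72 the value was higher in replicate 3, and 4 had opposite signs in the pair. Of the enriched windows, only those at PLEKHG6 and BPIFB1 reached log2 1 in both, and of the depleted ones 350 were at -1 or less in both. The central probes of the depleted windows had a median input signal of 146, averaged over replicates 2 and 3, against 894 for those of all windows. Leaving out replicate 2 or replicate 3 left 0 calls.

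Across the 3 replicates, 7 windows at 4 genes reached log2 1 in each array set, against 1.40 windows if the replicates were independent. These genes were named after their values were seen. The window at PLEKHG6 (probe on chromosome 12, 6288821 to 6288880, in the coordinates of the array files, whose genome build is not given in the sources used here) had ratios of 1.80, 1.36 and 1.70. BPIFB1, which encodes a secreted airway protein, had 1.19, 1.15 and 1.83. STIM1, a calcium sensor of the endoplasmic reticulum, had 3.55, 1.12 and 1.11, and RFX4, a transcription factor, had 2.55, 1.13 and 1.03. None of the 4 passed limma's test (adjusted p = 0.844 for each). On the opposite side, 38 windows were at -1 or less in all replicates, against 11.5 if independent.

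The replicates shared little of their ratios with the signals as processed. Across windows, which are not independent replicates, Pearson's r was 0.28 for replicates 1 and 2, -0.18 for replicates 1 and 3 and 0.03 for replicates 2 and 3. Spearman's rho was 0.31, -0.20 and 0.01 in the same order. The headers of the array files put replicate 1 in another scanning batch than replicates 2 and 3, and within that batch the single pair had r = 0.03. With normexp background correction the correlation of that pair was 0.40, that of replicates 1 and 2 was -0.12 and that of replicates 1 and 3 was -0.10. With the channels taken apart (log2 processed intensity across probes), the input of replicate 1 stood out most, with r = 0.82 against each of the other inputs, which had r = 0.96 with each other, and 0.83 against its own IP. The IP of replicate 1 had r = 0.89 with each of the other inputs, and 0.88 and 0.87 with the other IPs, which had r = 0.90 with each other. The SD of window ratios was 1.01 in replicate 1, 0.39 in replicate 2 and 0.48 in replicate 3. The highest 1% of windows of each replicate lay above 3.03, 0.74 and 0.97. Replicates 1 and 2 shared 100 of these, replicates 1 and 3 shared 52, and replicates 2 and 3 shared 48, against 42.5 by independent choice.

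Ratios around transcription starts also differed in direction. Within 500 bp of a start the median ratio was -0.32 in replicate 1, -0.28 in replicate 2 and 0.09 in replicate 3. More than 2000 bp away it was 0.37, 0.06 and -0.10. Ratios followed probe length in the same directions. Short probes had medians of -0.41, -0.17 and 0.15 in replicates 1 to 3, and long probes 0.65, -0.03 and -0.29. Whether probe length accounts for the profile around starts was not tested. Of the windows within 500 bp, 0.299% were in the highest 1% of replicate 1, 0.394% in that of replicate 2 and 1.73% in that of replicate 3. In the highest windows of replicate 1, 37.4% of probes had an input signal not well above background, against 4.46% and 4.86% in the highest windows of replicates 2 and 3.

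**Figure D1:**
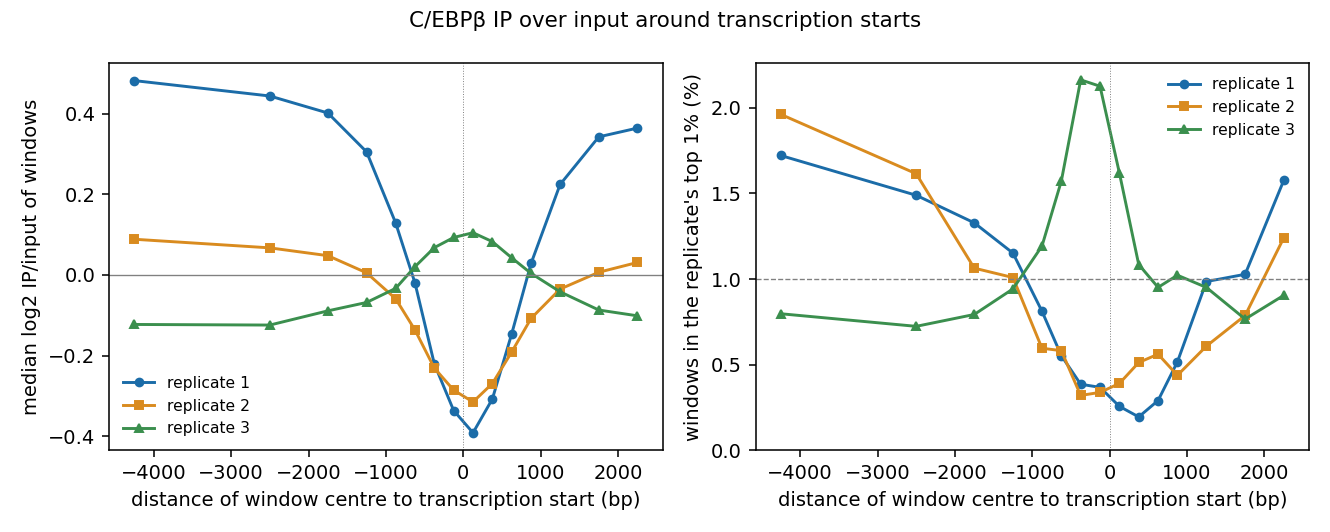
Median log2 IP/input (left) and the percentage of windows in a replicate's own highest 1% (right) by distance from the transcription start in bp, with 1 line per replicate and a dashed line at 1%. Replicates 1 and 2 dip at the start (medians of -0.32 and -0.28 within 500 bp), and replicate 3 peaks there (0.09).

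Among the 15 gene lists fixed in advance, 0 held a called gene, so Fisher's exact test had nothing to compare, and 0 windows were called when adjusted over the list alone in any list. The acute-phase genes (22 with a window) had median gene ratios of 0.57, 0.15 and -0.01 in replicates 1 to 3. Limma's camera test placed them above other genes with its preset correlation (adjusted p = 0.000235), but not with an estimated correlation (adjusted p = 0.985 with an estimated correlation). With the preset the call held in 7 of 7 settings (camera adjusted p from 1.07e-05 to 0.0106), and at 0.00301 without replicate 1. The olfactory receptors, a control list, were also called in 7, in 6 of them in the main direction. FGG, a fibrinogen chain, had 1.39 ± 1.43 at its highest window and LBP, the lipopolysaccharide-binding protein, 1.30 ± 1.98 (SD, n = 3), and without replicate 1 they were at 0.56 and 0.16. Of the 22 genes, 6 were above 0 in all 3 replicates, against 11.2% of all genes.

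Myeloid genes, listed as markers of another cell type, had medians of 0.20, 0.21 and 0.07 and were placed above other genes by camera's preset (adjusted p = 0.00515), but not with an estimated correlation (adjusted p = 0.985 with an estimated correlation). Of 23 genes, 10 were above 0 in all 3 replicates. CSF2RA, a cytokine receptor chain, had 1.87 ± 2.20 and MMP8, the neutrophil collagenase, 1.58 ± 1.67, and without replicate 1 they were at 0.60 and 0.63. The camera call for this list was lost without replicate 2 (adjusted p = 0.35), without replicate 3 (adjusted p = 0.141) and with normexp (adjusted p = 0.249), in a range of 7.04e-06 to 0.35 over its alternatives with the preset. Olfactory receptor genes, a control list of 293, were also placed above other genes by the preset (adjusted p = 0.000109; adjusted p = 0.985 with an estimated correlation). Their medians were 0.89, 0.07 and -0.35, and without replicate 1 the direction turned to below other genes (adjusted p = 0.0142). OR2T1 and OR4K13 had 1.66 ± 1.83 and 1.62 ± 2.10, and 0.62 and 0.41 without replicate 1.

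Cell cycle and apoptosis genes (35) were placed below other genes by camera's preset (adjusted p = 0.0156), but not with an estimated correlation (adjusted p = 0.985 with an estimated correlation). Their medians were 0.04, -0.16 and -0.06. The call was lost without replicate 1 (adjusted p = 0.333), without replicate 2 (adjusted p = 0.186) and with normexp (adjusted p = 0.207), in a range of 0.00983 to 0.333 over its alternatives with the preset. At their highest windows CDKN2A, a cell cycle inhibitor, had 1.74 ± 2.44 and GADD45A, a DNA damage response gene, 1.25 ± 1.45, and without replicate 1 they were at 0.35 and 0.42.

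The other 11 lists did not pass camera's preset test, with adjusted p from 0.143 (plasma proteins and apolipoproteins) to 0.949 (ribosomal proteins, the second control list). With normexp and the same preset, 3 of these passed at an adjusted p of 0.00326 each. They were the xenobiotic and cytokine lists, placed above other genes, and the liver transcription factors, placed below. Each passed in only 1 of 7 settings of the preset, and none on the main signals without it (adjusted p = 0.985 with an estimated correlation). For the C/EBP and related factors and the ribosomal proteins the test pointed below other genes while the mean of the 3 medians was above 0 (0.02 and 0.08). The windows named for these lists had their highest ratio in replicate 1. They were picked for their highest mean, which favours the replicate with the widest spread. Examples are HNF4A, a liver transcription factor (3.88, -0.03 and 0.16 in replicates 1 to 3), UGT1A1, which conjugates bilirubin (4.04, 0.33 and 0.70), ARG1, the urea cycle arginase (4.32, 0.14 and -0.18), PPARG, the adipogenic receptor (3.42, 0.33 and 0.93), and RPS18, a ribosomal protein (3.27, 0.09 and 0.39). Without replicate 1, ARG1 stood at -0.017, FETUB, a liver secretory protein, at -0.32, HNF4A at 0.066, UGT1A1 at 0.52, PPARG at 0.63 and RPS18 at 0.24. Over all 44 named genes the median was 1.30, and 0.41 without replicate 1, with 41 of them more than 1.5 times lower. With normexp, whose offset pulls ratios toward 0, the median was 0.14, with all 44 more than 1.5 times lower. At 9 of the 44, among them FGG, ALB, HNF4A, CDKN2A and OR4K13, 50% or more of the window's probes had an input signal in replicate 1 not well above background, so the size of that ratio is uncertain.

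The lists were then counted in the highest 1% of windows of each replicate, a description of single libraries that was chosen after the data were seen and that carries no p. In replicate 3, 10 of 23 genes of the unfolded protein and amino acid stress response had such a window, against a mean of 2.16 in 10000 random lists matched on windows per gene, and 0 random lists reached 10. The counts in replicates 1 and 2 were 0 and 3, against means of 2.63 and 2.54. The count in replicate 3 was 7 with loess (reached by 51 lists), 7 with normexp (10 lists) and 5 in the highest 0.5% of windows (43 lists). Members in replicate 3 included PPP1R15B, a phosphatase subunit (-0.61, -0.40 and 1.66 in replicates 1 to 3), CHAC1, which degrades glutathione (0.55, -0.49 and 1.37), TRIB3, a pseudokinase (-1.32, -1.08 and 1.23), and ASNS, asparagine synthetase (-0.40, -0.63 and 1.00).

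Plasma proteins and apolipoproteins had 10 of 31 members in the highest windows of replicate 3, against a random mean of 2.82, again with 0 of 10000 lists reaching it, and 5 and 4 in replicates 1 and 2, against means of 3.25 and 3.11. The count in replicate 3 was 8 with loess (reached by 56 lists), 6 with normexp (231 lists) and 6 in the highest 0.5% of windows (35 lists). APOA2, an apolipoprotein of high-density lipoprotein, had -0.17, 0.09 and 1.79 in replicates 1 to 3, at a window also annotated to TOMM40L. Hepatic lipase (LIPC) had -0.85, 0.33 and 1.76, and the retinol carrier RBP4 -0.24, -0.12 and 1.31. Acute-phase genes counted 6 of 22 in replicate 3 (random mean 2.01, reached by 126 lists), with fibrinogen FGA at -0.06, 0.40 and 1.75, and 2 and 3 in the other replicates. Complement and coagulation genes counted 7 of 37 (3.18, reached by 372 lists), with C3 at 0.48, 0.29 and 1.94, and 2 and 1 in the others.

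**Figure D2:**
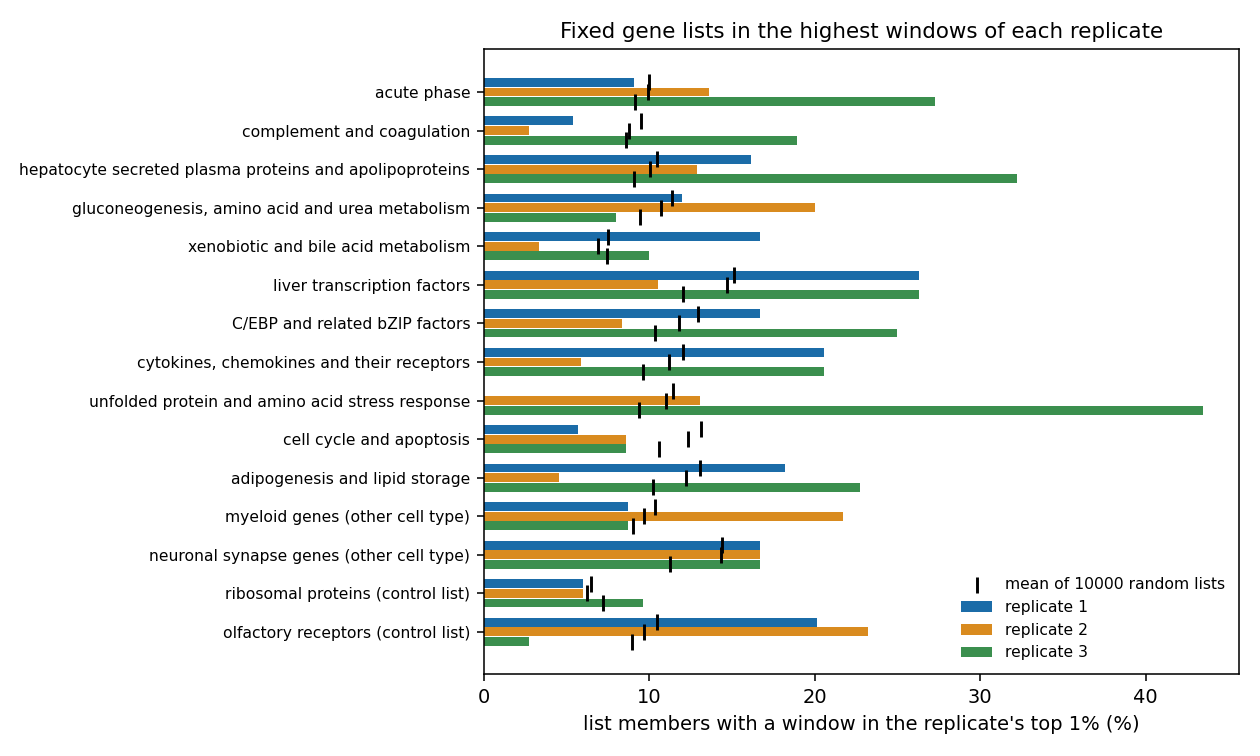
Percentage of each fixed list's members with a window in the highest 1% of a replicate (bars, 1 colour per replicate) and the mean of 10000 random lists of the same size (black ticks). The stress response list reaches 10 of 23 and the plasma protein list 10 of 31 in replicate 3, and the olfactory receptor list is above its tick in replicates 1 and 2 and below it in replicate 3.

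C/EBP and related factors counted 6 of 24 in replicate 3 (random mean 2.48, reached by 309 lists), with NFIL3, a repressor of the same protein class, at -0.14, 0.02 and 2.22, ATF3 at -0.48, -0.42 and 1.39, and a CEBPB window at 0.04, -0.27 and 1.47. They counted 4 and 2 in replicates 1 and 2. The list of cytokines, chemokines and their receptors counted 7 of 34 (3.27, reached by 420 lists), with the interleukin-6 receptor IL6R at -0.12, -0.63 and 2.40. It also holds genes outside that class, among them the NF-κB inhibitor NFKBIA, at -0.56, -0.76 and 4.15. The counts of this list in replicates 1 and 2 were 7 and 2. Liver transcription factors (5 of 19) and adipogenesis genes (5 of 22) were reached by 702 and 671 random lists in replicate 3. Gluconeogenesis (2 of 25), xenobiotic metabolism (3 of 30), cell cycle (3 of 35), myeloid (2 of 23), neuronal synapse (5 of 30) and ribosomal protein genes (8 of 83) were reached by 2424 to 7335 lists.

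Olfactory receptors went the other way. They counted 59 and 68 of 293 in replicates 1 and 2, against random means of 30.7 and 28.3 that 0 lists reached, and 8 in replicate 3, against a mean of 26.2. In all, 45 such counts were made, and none tests a difference between replicates.

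**Figure D3:**
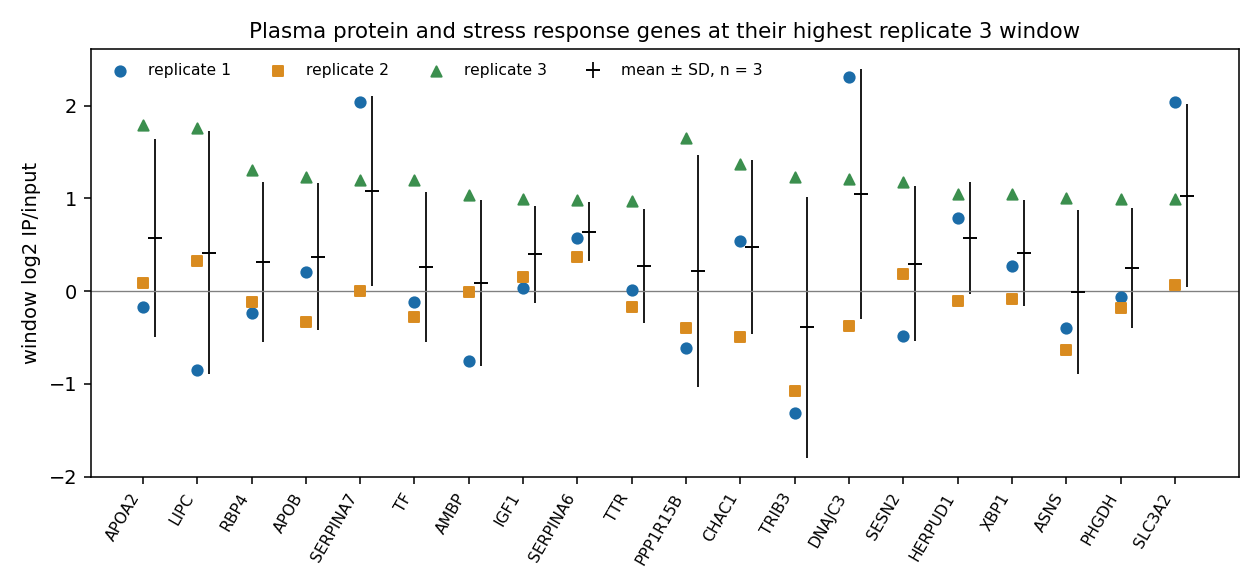
Log2 IP/input of the plasma protein genes (left 10) and stress response genes (right 10) at their highest window of replicate 3, with points for the 3 replicates and a bar for the mean ± SD (n = 3). The genes and windows were picked for their replicate 3 value, so its height there is given by that choice, and the values of replicates 1 and 2 run from -1.32 (TRIB3) to 2.31 (DNAJC3), both in replicate 1.

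The deposited value table holds 1926 probes at 1140 genes, with column medians of 0.40, 1.72 and 0.05. Its column for replicate 1 followed the array file of replicate 1 (r = 0.97 across probes). The column labelled replicate 2 followed the array file labelled replicate 3 (r = 0.93), and the column labelled replicate 3 followed that labelled replicate 2 (r = 0.92). The correlations with the files of their own number were -0.04 and -0.05. Replicate numbers in the present text are those of the array files. Of the tabled probes that centre a window, 65.2% were in the highest 1% of replicate 3, against 1.42% and 1.11% for replicates 1 and 2. The table held 7 of 22 acute-phase genes (random mean 1.49, reached by 6 of 10000 lists), 8 of 37 complement and coagulation genes (2.23, reached by 13) and 6 of 23 stress response genes (1.57, reached by 46). Plasma proteins counted 5 of 31 (reached by 579 lists) and C/EBP and related factors 5 of 24 (351), while the olfactory receptors counted 8 of 293 against a mean of 19.0 (9990), and the other 9 lists were reached by 846 to 7781. These counts are not independent of those for replicate 3. Limma on the 3 columns called 5 enriched probes, named after their values were seen, at FAM111A, B4GALT2, CLCN4, PID1 and ANKRD1 (smallest adjusted p = 0.00096, 250 probes under an unadjusted p of 0.05), and 0 depleted. The probe at FAM111A was high in all 3 columns (4.42, 3.24 and 4.72), and the other 4 had 6.98 to 8.55 in the column for replicate 1 and 0.51 to 1.88 in the others. In the array files the same FAM111A probe had 3.01, 0.49 and 2.16 in replicates 1 to 3. Its height in the column labelled replicate 3 was thus not seen in the matching array file, that of replicate 2. The other 4 had 3.25 to 5.65 in the array file of replicate 1. How the tabled probes were chosen is not recorded, and 99.9% were above 0 in the column labelled replicate 2, so the test was not made on an unselected set.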

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

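Array weights, scaling to equal spread, centring within probe length, normexp for the correlations, the single-probe test with a replicate left out and all camera alternatives except the estimated correlation were chosen after seeing the data. Of 23 alternatives, 4 could not move the counts (other thresholds on the same p-values, and saturated spots left out). Among the other 19, the count of 0 enriched windows held in 16, that of 0 depleted windows in 17 and that of 0 bound genes in 16. Leaving out 1 replicate each gave 0 to 72 enriched windows, 0 to 1030 depleted windows and 0 to 40 bound genes, all calls coming from the fit without replicate 1, where limma gave every window the same spread. In 100 copies with replicate 3 shifted along the genome, the refitted model called at most 1 enriched and 7 depleted windows. The spread was estimated anew in each copy, and whether it was again the same for every window was not recorded. The copies therefore cannot tell whether the calls come from shared signal or from the equal spread. Single probes without replicate 1 gave 0 enriched (5764 above 0 at an unadjusted p under 0.05). Limma's array weights did not converge. They put a weight of 255 on replicate 2 against 0.045 and 0.087 on replicates 1 and 3, and called 662 enriched windows, 4796 depleted windows and 318 genes, in effect a test of 1 array set, so these counts are not used. The deposited table gave 5 enriched probes and 5 genes among 1926, where fewer probes were tested. Unpaired channels, with no replicate block, gave 0 enriched, 0 depleted and 0 bound. With an estimated correlation camera called 0 lists in place of 4. Its preset correlation called 2 to 3 with 1 replicate left out. With normexp the correlation of replicates 1 and 2 became -0.12 and that of replicates 2 and 3 0.40, and the cause was not tested. Of 306 alternative values for the named genes, 301 kept their sign and none passed the test, but the value fell by more than 1.5 times at 41 of 44 genes without replicate 1, at 44 with normexp, at 19 with loess and at 26 of 42 in windows of 1000 bp. It rose by more than 1.5 times at 8 genes without replicate 2 and at 7 without replicate 3, where 1 fell (CEBPB). The falls with normexp come in part from its offset, which pulls ratios toward 0. Those without replicate 1 come in part from picking windows by their highest mean, which favours the replicate with the widest spread. With 1 replicate left out, ARG1 ranged from -0.017 to 2.23, CEBPD from -0.27 to 1.24, CXCL8 from -0.027 to 1.34 and FETUB from -0.32 to 2.25, each lowest without replicate 1. In windows of 1000 bp CEBPB was at -0.057. Dim input limits replicate 1 most, with 14.3% of the probes in its windows not well above background.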

Other observations

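The tests of probe length, position near starts, exchanged columns and sign assignments were chosen after the patterns were seen. The settings for dim spots and dye bias were fixed in advance, but the bound they were held to was set after the correlations were seen.

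The 3 replicates shared little of their window ratios, with r from -0.18 to 0.28. If dim spots were the cause, probes well above background should have agreed, but there the lowest of the 3 correlations was -0.16 and the highest 0.36. These values argue against dim spots as the whole source. Loess within each array, against an intensity-dependent dye bias, moved the lowest from -0.18 to -0.044. Centring within probe length, a stand-in for GC content, moved it to 0.0197. Both took away most of the negative correlation of replicates 1 and 3, but neither made the replicates agree. Probe length only stands in for GC content, and loess removes only a bias that follows intensity, so dye and GC bias are not excluded. With normexp in place of the processed signals, however, the pair of replicates 2 and 3 rose from 0.03 to 0.40 while the others were at -0.12 and -0.10. Normexp started from the scanned signals, so it also left out the detrending of the processed ones, and it added an offset. Background correction, detrending and offset were not separated and remain open for that pair. Between the channels, the input of replicate 1 agreed least with the others (r = 0.82 with each other input), less than the IP of replicate 1 did with the same inputs (0.89), but this leaves the pair of replicates 2 and 3 unexplained. Differences in labelling, amplification or precipitation may remain and were not separated, and all replicates belong to 1 group, so no biological explanation was tested.

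In replicate 3 the stress response and plasma protein lists had 10 of 23 and 10 of 31 members in the highest windows. Centred within probe length, the counts were 9 and 12, and at most 0.02% of random lists reached either, which argues against probe length as the whole source. Counting only windows within 500 bp of a transcription start gave 6 of 23 and 7 of 30, reached by at most 0.01% of random lists, which argues against position near starts as the whole source. Both checks were run on these lists alone, which were picked for their counts. The olfactory receptors, a control list, were as extreme in replicates 1 and 2 (59 and 68 of 293, reached by 0 random lists). Random lists were matched on windows per gene only, so other differences between kinds of promoter stay open. C/EBPβ at these promoters in that library is a candidate explanation that may be followed up, but replicates 1 and 2 do not share the pattern, and without a mock precipitation an antibody-independent signal stays open. No biological explanation was tested.

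The deposited columns labelled replicates 2 and 3 matched the array files of the other number, with the lower crossed correlation at 0.92 and the own correlations no higher than -0.04. This is consistent with an exchange of the labels of either the columns or the files, and which of them carries the right number cannot be read from the values. The window test takes the replicates in any order and is not affected.

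With 3 replicates there are 4 assignments of signs, and all 4 gave 0 called windows, the real value being 0 and the highest other 0. So few assignments cannot give a share under 0.05. At an unadjusted p under 0.05 the real signs gave 10256 windows and the others 15550, 2475 and 21433, the highest with replicate 3 turned around.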
